A study of Rattus norvegicus with 4 samples.

How the data were processed

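Total RNA of 2 Dunning rat prostate tumour lines, G and MAT-LyLu, was hybridised as biotinylated cRNA to Affymetrix oligonucleotide arrays, with 2 arrays per line and 4 arrays in all. The lines were taken from the sample titles. The authors deposited 1 table of probe set signal intensities, 1 column per array, and the submitters' processing notes name MAS5, the Affymetrix algorithm that combines the probes of a probe set into 1 signal. The version, the scaling target and any filter on the signals are not given in the sources used here. The deposited intensities were linear and positive, with array medians from 2998 to 3156. The 2% trimmed means (2% taken off each tail) of the arrays ran from 4928 to 5314 and differed by at most 7.83%, under the 10% limit above which a further scaling had been planned, so the main values were used without further normalization.

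The table held 8799 probe sets, of which 59 were array controls. Names came from the platform annotation as given in the probe table, with symbols updated through the gene identifiers of the GRCr8 RefSeq table. One gene symbol was available for 7018 probe sets, several for 308, and none for the other 1473; 6994 of the 7018 were matched in the RefSeq table. A probe set with several symbols or none was counted in the probe set totals and never named. The array's own genome build is not given in the sources used here, so no coordinates are printed. Genes that no named probe set covered, such as Cdh1, were not analysed here.

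Values were tested on the scale log2(signal + 16). Control probe sets and the 25% of the remaining probe sets with the lowest mean over the 4 arrays were left out, which left 6555. MAT-LyLu was compared with G with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), 2-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene below comes from this limma test. For genes, the tested probe set with the highest mean over the 4 arrays stood for its gene, and 3867 genes were tested and adjusted on their own. With 2 arrays against 2 the permutation of a single value cannot reach a small p, and the adjusted p-values rest on the variance that limma pools over probe sets. The labels speak of duplicates and name no separate cultures, so the p-values measure the spread between these arrays, which may be technical.

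Both limits of the signal scale, background and saturation, were set after the values had been seen. The background level of an array was the 95th percentile of its 23 bacterial, yeast and mouse control probe sets, which ran from 1891 to 2311, and 33.8% to 40.4% of the rat probe sets lay under it. A probe set under it on both arrays of a line has only a bound there, and its fold is written "at least", computed with the dim values raised to the background level of their array. Signals within 5% of an array's highest value were taken as saturated; 43 tested probe sets reached that on at least 1 array. Folds of probe sets that end in _s or _f can include related transcripts. Besides genes marked below, such probe sets read Serpine2, Sdc1, Cd44, Ifitm3, Oas1a, Ccl2, Ptgs1, Clu, Akr1c14, Timp2 and Gsta1. They also read Atp5pd, Rpl30, Hspb1, Ddc, Myh4 and Scn9a.

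In all, 25 gene lists were fixed before the data were examined, together with the tests and the rule for the genes to be named. The rule took the 12 genes with the largest fitted rise and the 12 with the largest fitted fall among those past the threshold whose 2 MAT-LyLu arrays lay on one side of both G arrays, up to 4 members of each list with the smallest p, and 10 genes given in any case, of which 8 were measured. Lists were tested against all other genes with limma's camera (inter-gene correlation preset to 0.01, Benjamini-Hochberg over the 25 lists), and again with an estimated correlation. They were also tested with fry, which asks whether a list's own genes show a net change up or down. Fry makes no comparison with other genes, so a fry call alone does not set a list apart from them. The estimated correlation rests on 2 residual degrees of freedom. A call lost with it, for a list, family or chromosome, neither shows nor excludes that correlation among genes undid that call. The lists were matrix, proteases, epithelial, mesenchymal, integrin, actin, cell cycle, p53, glycolysis, interferon, cytokine, growth factor, TGF-beta and Wnt, androgen, ion channel, metastasis suppressor, glutathione, sterol and fatty acid, respiratory chain, ribosomal, protein folding, endothelial, leukocyte, neuronal and muscle genes. Alternatives were the pseudocount (1 and 64), the filter (none, and the lower 50% left out), quantile and median scaling, the variance model, the replicate number as a block, each array left out in turn, a test against a minimum log2 difference of 1 and the mean of all probe sets of a gene. A floor at the background level, removal of saturated probe sets and cyclic loess scaling were added after seeing the data.

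The limma script was tested on simulated arrays with 200 seeded changes among 6555 probe sets. It called 61.2% of the 67 changes of 0.5 on the log2 scale, 98.5% of the 67 changes of 1 and 100% of the 66 changes of 2, and 12 of its 185 calls were false. In simulated arrays with 1 list of the 25 shifted by 0.3, camera called that list and no other. The simulated genes varied independently, so this run could not show false list calls that come from correlated genes. Figures were drawn with matplotlib 3.10.9.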

Results

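Gene expression was measured on 4 oligonucleotide arrays, 2 of the G line and 2 of the MAT-LyLu line. Both are sublines of the Dunning rat prostate tumour. G is described by the submitters as non-metastatic and MAT-LyLu as highly metastatic, and the single comparison of the design asked which genes differ between them, with G as the control. Array medians were 3156 and 3049 signal units in G and 2998 and 3015 in MAT-LyLu. Across the 6555 probe sets tested, log2 signals of the 2 G arrays correlated at r = 0.990 (rho = 0.989) and those of the 2 MAT-LyLu arrays at r = 0.990 (rho = 0.988), against r from 0.822 to 0.829 between the lines; probe sets are not independent replicates. The SD of the log2 difference was 0.18 between the G arrays, 0.17 between the MAT-LyLu arrays and 0.71 to 0.72 between arrays of different lines. Signals below are means ± SD over the 2 arrays of a line, and log2 differences (MAT-LyLu minus G) carry the standard error (SE) of the limma fit. The number of arrays limits their precision.

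MAT-LyLu cells had higher signals than G cells for Krt8, Cav1, Fabp4 and Msmo1. They had lower signals for Lum, Eln and the fibrillar collagen genes Col1a1, Col1a2 and Col3a1. Krt8 rose 22.5-fold, with 1 of the 2 G arrays above background, and Lum fell at least 14.6-fold. Of 6555 probe sets, 891 were higher and 1318 lower in MAT-LyLu at an adjusted p under 0.05, and 237 and 311 of these differed by 2-fold or more. Among 3867 genes, 557 were higher and 792 lower, with 134 and 169 at 2-fold or more; with quantile normalization 707 were higher and 694 lower, so the excess of falls among genes rests on the scaling. The median log2 difference of all tested genes was -0.02. The lines' arrays did not overlap for 67.4% of the probe sets, where chance gives 33.3%.

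Of the 12 genes with the largest fitted rises (adjusted p from 6.0e-10 to 4.3e-09), 11 were under the background level on both G arrays, so their rises are bounds and have no measured order. Fabp4, a fatty acid carrier, rose from 879 ± 65.5 to 29801 ± 803, at least 14.4-fold. Cav1, the main protein of caveolae, rose from 894 ± 8.33 to 27758 ± 88.2, at least 13.4-fold. Penk, the enkephalin precursor, rose at least 15.5-fold, and Tmsb4x, the actin-sequestering thymosin beta-4, at least 18.7-fold. Krt8, a keratin of simple epithelia, rose 22.5-fold from 1835 ± 203 to 41478 ± 60.8, with 1 of the 2 G arrays above background. The surface glycoproteins Cd24 (at least 7.67-fold) and Spn (at least 6.27-fold), the proteoglycan Esm1 (at least 6.88-fold), the fatty acid desaturase Scd (at least 6.80-fold), the asparagine synthetase Asns (at least 3.81-fold), Pgrmc1 (at least 4.72-fold) and Klhl41 (at least 6.98-fold) completed this group. Penk and Krt8 were read by probe sets that can match related transcripts.

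Of the 12 genes with the largest fitted falls (adjusted p from 5.3e-10 to 1.1e-06), 10 were under the background level on both MAT-LyLu arrays, and their falls are bounds likewise. Genes measured in both lines and outside these 24, such as Msmo1 and Clu below, had folds above some of the bounds. Lum, which encodes the collagen-binding proteoglycan lumican, fell from 30791 ± 1195 to 437 ± 23.0, at least 14.6-fold. The fibrillar collagen genes Col1a2 (at least 14.2-fold), Col1a1 (16.2-fold, from 43732 ± 5644 to 2673 ± 97.0) and Col3a1 (10.8-fold, with 1 of the 2 MAT-LyLu arrays above background) fell, as did Eln, the elastin gene (at least 11.3-fold). Ptgds, a prostaglandin D synthase, fell at least 9.30-fold, the lactate dehydrogenase subunit Ldhb at least 8.35-fold, the deubiquitinase Uchl1 at least 9.75-fold and the tetraspanin Cd81 at least 7.79-fold. Ass1, of the urea cycle, fell at least 6.12-fold, the cathepsin Ctsh at least 4.88-fold and the coagulation inhibitor Tfpi at least 2.52-fold. Col1a1, Col1a2, Col3a1, Uchl1 and Tfpi were read by probe sets that can match related transcripts. All 24 genes kept their direction and passed the threshold in every alternative run that tested them. Those runs reuse the arrays that picked the genes for their large differences, so this is no separate support for them.

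**Figure D1:**
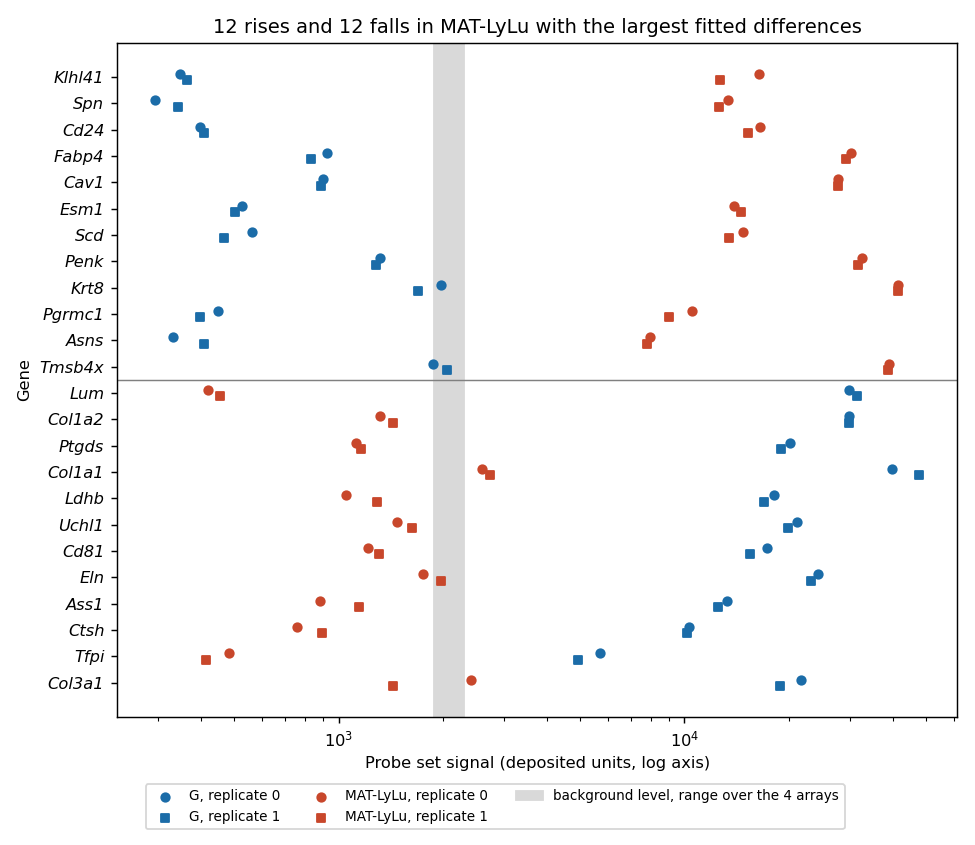
Signal of each array (log axis, deposited units) for the 12 genes with the largest fitted rises and the 12 with the largest fitted falls in MAT-LyLu; circles are replicate 0 and squares replicate 1 of each line, and the grey band is the range of the background level over the 4 arrays. The arrays of a line lie close together, and the dim line is at or under the band for most genes, with Lum at 437 in MAT-LyLu against 30791 in G.

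Genes of cholesterol and fatty acid synthesis were higher in MAT-LyLu. Of 21 members measured, 15 rose, 1 fell and 5 did not pass (15 and 2 adjusted over the list alone), with a median log2 difference of 0.64. Msmo1, a sterol C4 methyl oxidase, rose 16.7-fold from 1898 ± 177 to 31939 ± 247 (log2 difference 4.06, SE 0.09, adjusted p = 2.2e-09), with 1 of the 2 G arrays above background, and Fdps, the farnesyl diphosphate synthase, rose 4.04-fold from 7281 ± 93.4 to 29574 ± 2959. Scd rose at least 6.80-fold. The member that fell was Srebf1, a transcription factor of lipid synthesis, at 3.15-fold lower (23260 ± 1772 against 7362 ± 310). The list stood apart from all other genes by camera (adjusted p = 3.3e-06), and the adjusted p = 0.80 with an estimated correlation did not pass.

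Interferon response and antigen presentation genes were lower in MAT-LyLu. Of 18 members measured, 11 fell, 1 rose and 6 did not pass, with the same 11 and 1 adjusted over the list alone and a median log2 difference of -0.80. Ifitm3, an interferon-induced membrane protein, was 8.12-fold lower (23690 ± 565 against 2904 ± 19.7). The interferon regulatory factor Irf7 was 6.09-fold lower, the antiviral GTPase Mx1 at least 3.01-fold lower and the oligoadenylate synthetase Oas1a 3.87-fold lower, with adjusted p-values from 4.6e-09 to 1.2e-07. B2m, the light chain of class I molecules, was 3.74-fold lower. The member that rose was the chemokine Cxcl10, with a log2 difference of 0.37 (SE 0.08). The class II genes RT1-Da and RT1-Ba and the invariant chain Cd74 did not pass, with log2 differences of 0.06, -0.01 and -0.09. B2m, Cxcl10 and these 3 genes were named after their values were seen. By camera the adjusted p was 3.6e-05, and the adjusted p = 0.80 with an estimated correlation did not pass.

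Genes of the mitochondrial respiratory chain were lower in MAT-LyLu. Of 20 members measured, 13 fell and none rose at an adjusted p under 0.05 in limma, nor did any rise at an unadjusted p under 0.05; 14 fell adjusted over the list alone, and the median log2 difference was -0.58. The ATP synthase subunit Atp5f1c was 2.39-fold lower (26115 ± 1247 against 10948 ± 1118, adjusted p = 1.0e-05). The complex I subunit Ndufv2 was 1.61-fold lower, and the ATP synthase subunits Atp5pd and Atp5pb were 1.63-fold and 1.67-fold lower. The list passed by camera (adjusted p = 0.0012) and by fry (adjusted p = 0.045), and the adjusted p = 0.80 with an estimated correlation did not.

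Matrix genes were lower on balance. Of 20 members measured, 9 fell, 3 rose and 8 did not pass (10 and 3 adjusted over the list alone), and 8 of the falls were of 2-fold or more. Besides Lum, Col1a2, Eln and Col1a1, the small proteoglycan genes Bgn (6.10-fold) and Dcn (at least 5.26-fold) fell. The members that rose were Spp1, or osteopontin, at 4.12-fold, Fn1, or fibronectin, at 2.92-fold (8499 ± 734 against 24861 ± 3031), and Vcan, or versican, at 1.66-fold. Bgn, Dcn, Spp1 and Vcan were named after their values were seen. By camera the adjusted p was 0.042, and it was 0.80 with an estimated correlation; leaving out the lower 50% of the probe sets moved it from 0.042 to 0.054. Sparc, whose brightest probe set did not pass, had 3 of 4 probe sets lower.

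Among mesenchymal markers, 7 of 17 measured fell, 3 rose and 7 did not pass, with the same counts adjusted over the list alone. Col1a1, Col3a1 and Thy1, a surface glycoprotein of fibroblasts (at least 3.38-fold), fell, and S100a4, a calcium-binding protein linked to cell motility, rose 4.71-fold from 8763 ± 836 to 41223 ± 861. Vim, or vimentin, was bright in both lines (45257 ± 9357 in G and 37866 ± 590 in MAT-LyLu) and did not pass (log2 difference -0.24, SE 0.14, adjusted p = 0.24). The G arrays differed for Vim, at 38640 and 51873, and without G replicate 0 it passed at a log2 difference of -0.45 (adjusted p = 0.0011), while without G replicate 1 the difference was -0.029 (adjusted p = 0.79). The list did not pass camera (adjusted p = 0.14), and it passed fry (adjusted p = 0.0013).

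Protease and inhibitor genes changed in both directions. Of 24 members measured, 7 rose, 11 fell and 6 did not pass, with the same counts adjusted over the list alone. Serpine2, an inhibitor of serine proteases, rose 8.55-fold from 2511 ± 91.0 to 21587 ± 84.0, and Plau, the urokinase plasminogen activator, rose at least 3.31-fold. Mmp14, a membrane-bound metalloproteinase, fell 5.52-fold from 38137 ± 2846 to 6923 ± 1003. Mmp2 and Mmp9, the gelatinases, did not pass, with log2 differences of -0.17 (SE 0.10) and 0.08 (SE 0.10). The list did not pass camera (adjusted p = 0.50), and it passed fry with the direction down (adjusted p = 0.029).

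Epithelial and adhesion genes included rises of Krt8, Cd9 and Sdc1. Of 11 junction and keratin genes measured, 3 rose, 1 fell and 7 did not pass, with the same counts adjusted over the list alone. Krt8 and Spint2, a protease inhibitor of epithelia (4.23-fold, from 3931 ± 149 to 16696 ± 242), were the larger rises. The third rise, Tjp1, lost its call without G replicate 1 (adjusted p = 0.073) and without MAT-LyLu replicate 0 (0.084). The fall, Jup, lost its call under quantile, median and loess scaling (0.051 to 0.089) and without G replicate 1 (0.14), MAT-LyLu replicate 0 (0.15) or MAT-LyLu replicate 1 (0.12). Krt18, the usual partner of Krt8, had signals near the background level in both lines, at 1733 ± 398 and 1725 ± 207, and did not pass; it was named after its values were seen. Of 19 integrins and adhesion receptors, 6 rose, 2 fell and 11 did not pass, with the same counts adjusted over the list alone. The tetraspanin Cd9 rose at least 7.32-fold, the proteoglycan Sdc1 5.05-fold, the hyaluronan receptor Cd44 2.87-fold (4129 ± 61.8 against 11882 ± 938) and the tetraspanin Cd151 2.87-fold. Neither list passed camera (adjusted p = 0.16 and 0.10), and both passed fry with the direction up (adjusted p = 0.029 each). The junction and keratin list had a median log2 difference of 0.0066, and Krt8 and Spint2 were its only members changed by 2-fold or more.

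Of 25 actin cytoskeleton genes measured, 12 rose, 4 fell and 9 did not pass, with the same 12 and 4 adjusted over the list alone. After Cav1, the ezrin gene Ezr rose 2.16-fold and the tropomyosin gene Tpm4 2.02-fold, with 1 of the 2 probe sets of Tpm4 past the threshold, while the myosin light chain gene Myl9 fell 3.44-fold from 11180 ± 394 to 3243 ± 126. By camera the adjusted p was 0.042, and it was 0.97 with an estimated correlation. The median log2 difference of the list was 0.18 and its mean 0.38. Cav1 adds to that mean with a fitted 4.93, a value without exact size because G was under the background level. The list lost its camera call without G replicate 0 (adjusted p = 0.095), without MAT-LyLu replicate 0 (0.068), with no filter (0.069), with the lower 50% left out (0.054), with median scaling (0.074) and with the mean of all probe sets (0.056).

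**Figure D2:**
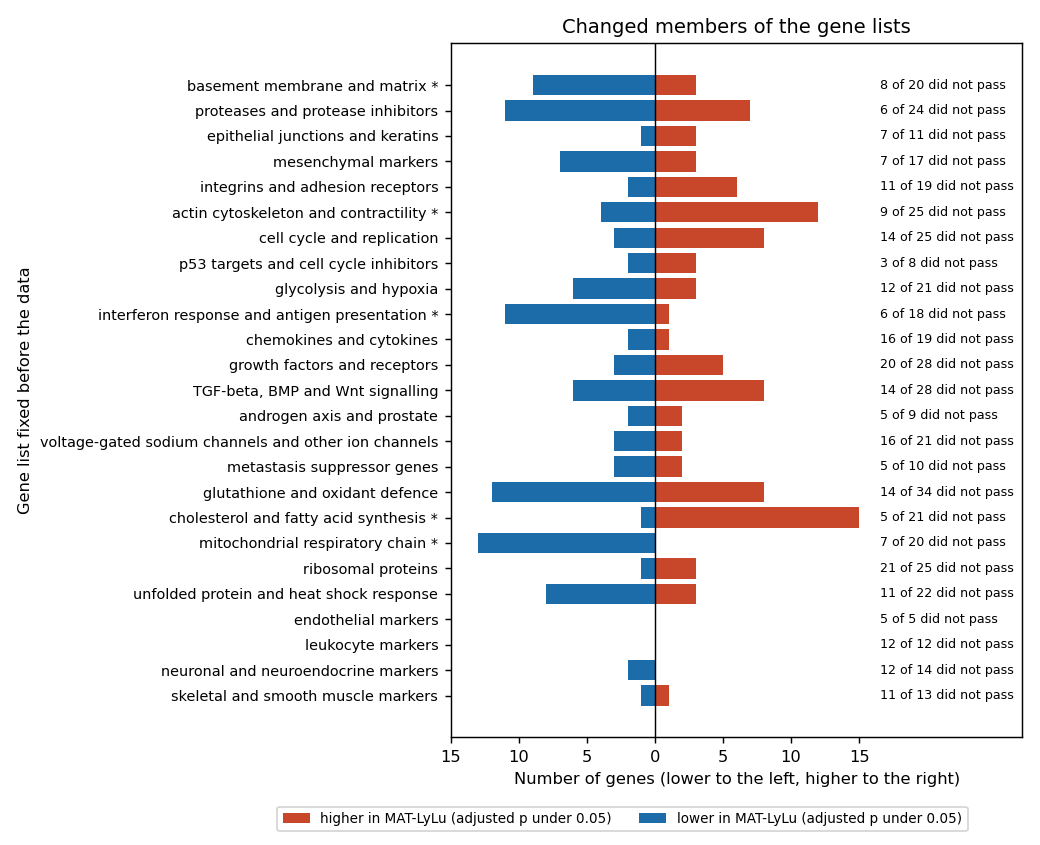
Number of genes of each list that were lower (blue, to the left) or higher (red, to the right) in MAT-LyLu at an adjusted p under 0.05, with the number that did not pass at the right; an asterisk marks the lists past 0.05 by camera. The sterol and fatty acid list has 15 rises and 1 fall, and the respiratory chain list 13 falls and no rise.

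Cell cycle genes changed in both directions. Of 25 genes measured, 8 rose, 3 fell and 14 did not pass, with the same counts adjusted over the list alone. Ccnd1, or cyclin D1, rose 7.90-fold from 3016 ± 560 to 23745 ± 1287 on its brightest probe set; 3 of its 5 probe sets rose and 1 fell. Ccnd3, or cyclin D3, fell 4.68-fold from 45214 ± 3376 to 9633 ± 244. Cdc20, an activator of the anaphase-promoting complex, rose 2.35-fold. The rise of Tyms lost its call with a floor at the background level (adjusted p = 0.23). The list did not pass camera (adjusted p = 0.25) or fry (adjusted p = 0.25). Of 8 p53 targets and cell cycle inhibitors, 3 rose, 2 fell and 3 did not pass; Btg1 rose 2.62-fold and Mdm2 1.81-fold (2 of its 3 probe sets), and Ccng1 fell 1.77-fold. The rise of Rbl2 lost its call without MAT-LyLu replicate 0 (adjusted p = 0.076) and with a floor at the background level (0.16).

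Growth factor and signalling genes changed in both directions. Of 28 growth factors and receptors measured, 5 rose, 3 fell and 20 did not pass. Igfbp5, an insulin-like growth factor binding protein, fell 5.21-fold, while the epidermal growth factor receptor ligands Hbegf (1 of 2 probe sets past the threshold) and Tgfa rose, Hbegf 2.21-fold and Tgfa from 4223 ± 639 to 8407 ± 608. Of 28 TGF-beta, BMP and Wnt genes, 8 rose, 6 fell and 14 did not pass. Fst, the activin antagonist follistatin, rose 5.82-fold, with 1 of the 2 G arrays above background, and Id2 3.83-fold, and the Wnt receptor genes Fzd2 and Fzd1 fell 3.75-fold and 2.55-fold. Of 19 chemokine and cytokine genes, 1 rose, 2 fell and 16 did not pass; the chemokine Ccl2 fell at least 4.03-fold and the cyclooxygenase gene Ptgs1 rose 5.66-fold, with 1 of the 2 G arrays above background. The other fall, Il6st, was under the background level in both lines, lost its call without G replicate 1 (adjusted p = 0.10), MAT-LyLu replicate 0 (0.10) or MAT-LyLu replicate 1 (0.077), and had a log2 difference of 0.024 with a floor at that level. For these lists and the p53 list the counts adjusted over the list alone were the same, and none passed camera (adjusted p = 0.61 for p53, 0.77 for growth factors, 0.34 for TGF-beta and Wnt and 0.77 for cytokines).

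In glutathione and oxidant defence, 8 of 34 genes measured rose, 12 fell and 14 did not pass. Aldh3a1, an aldehyde dehydrogenase, rose 5.75-fold from 4134 ± 58.9 to 23863 ± 58.1, Mgst2 rose 4.38-fold and the extracellular superoxide dismutase Sod3 3.35-fold, and Gsta1 fell 2.68-fold. In glycolysis and hypoxia, 3 of 21 rose, 6 fell and 12 did not pass. Besides Ldhb, the glucose transporter gene Slc2a1 rose 1.92-fold, and the phosphofructokinase genes went apart, with Pfkl 1.55-fold higher and Pfkm 1.60-fold lower. In the unfolded protein and heat shock list, 3 of 22 rose, 8 fell and 11 did not pass. After Asns, the heat shock genes Hsph1 and Hspb1 fell 5.55-fold and 2.69-fold, and 3 of the 4 probe sets of Hspb1 were lower. Of 25 ribosomal protein genes, 3 rose, 1 fell and 21 did not pass, and Rpl4 had the smallest p at 1.59-fold higher. The fall, Rpl30, lost its call with quantile normalization (adjusted p = 0.077) and without G replicate 1 (0.088), MAT-LyLu replicate 0 (0.055) or MAT-LyLu replicate 1 (0.099), and the rise of Rpl14 without MAT-LyLu replicate 0 (0.073). Adjusted over the list alone the counts were the same for these lists, and none passed camera (adjusted p = 0.77, 0.92, 0.50 and 0.92, in this order). By fry the glycolysis list passed with the direction down (adjusted p = 0.045). Its median log2 difference was -0.0044, and Ldhb was its only member changed by 2-fold or more. That call therefore does not show a fall across the list.

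Clu was lower in MAT-LyLu, and Cd44 was higher. Of 9 androgen and prostate genes measured, 2 rose, 2 fell and 5 did not pass (3 and 3 adjusted over the list alone). Clu, or clusterin, fell 8.80-fold from 24395 ± 115 to 2759 ± 7.04, and Akr1c14, a steroid dehydrogenase, fell at least 2.05-fold. Of 10 metastasis suppressor genes, 2 rose, 3 fell and 5 did not pass. Cd44 rose, Timp2 and Timp3, inhibitors of metalloproteinases, fell 2.63-fold and 1.90-fold while Timp1, of the protease list and named after its values were seen, rose 1.79-fold, and Nme1 did not pass (12090 ± 25.8 against 11415 ± 68.7, adjusted p = 0.48). Cd82, a tetraspanin, rose 1.40-fold (adjusted p = 0.0084), a call lost without MAT-LyLu replicate 0 (log2 difference 0.38, adjusted p = 0.094). Of 21 ion channel genes, 2 rose, 3 fell and 16 did not pass. Cacnb3 was 1.62-fold and Kcnh2 1.48-fold lower, and Clcn3 1.47-fold higher; 1 of the 2 probe sets of Kcnh2 passed. The third fall, Cacna1c, lost its call without G replicate 0 (adjusted p = 0.14), MAT-LyLu replicate 0 (0.062) or MAT-LyLu replicate 1 (0.17). Scn9a, a voltage-gated sodium channel, was under the background level on both G arrays and above it on 1 of the 2 MAT-LyLu arrays (1705 ± 6.52 and 2037 ± 138, adjusted p = 0.070); median scaling and quantile normalization moved its adjusted p to 0.035 and 0.040. None of the 3 lists passed camera (adjusted p = 0.92, 0.77 and 0.92), and by fry the androgen and metastasis suppressor lists passed with the direction down (adjusted p = 0.034 and 0.045). The androgen list had a median log2 difference of -0.012 and the camera direction up, and Clu was its largest fall. Its fry call therefore does not show a fall across the list. The metastasis suppressor list had a median log2 difference of -0.15, and 2 of its 10 members rose. Timp2 was its only called fall of 2-fold or more, so its fry call does not show a fall across that list either.

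Of the markers of other cell types, 4 passed the threshold. None of 5 endothelial and none of 12 leukocyte markers measured changed in limma, and none of either list had an unadjusted p under 0.05; neither list passed fry (adjusted p = 0.69 and 0.95). Of 14 neuronal and neuroendocrine markers, 2 fell, Uchl1 and the neurofilament gene Nefh (1.37-fold, in 1 of its 2 probe sets; adjusted p = 0.052 with the mean of its probe sets), and none rose, at an unadjusted p under 0.05 either; without G replicate 0, Ddc (adjusted p = 0.043) and Snap25 (0.013) passed as higher. Of 13 muscle markers, 1 rose and 1 fell. Myh4 passed while under the background level in both lines, a call lost with a floor at that level (0.94), and Ckm fell 1.22-fold (adjusted p = 0.043), a call lost with no filter (0.050), no intensity trend (0.052), quantile normalization (0.19), median scaling (0.083), cyclic loess (0.10) and without G replicate 1 (0.23), MAT-LyLu replicate 0 (0.23) or MAT-LyLu replicate 1 (0.088). Adjusted over the list alone the counts were the same except that Ckm did not pass. Camera gave adjusted p-values of 0.77, 0.92, 0.92 and 0.97 for the endothelial, leukocyte, neuronal and muscle lists. By fry the neuronal list passed with the direction down (adjusted p = 0.045). Its median log2 difference was 0.019 and Uchl1 was its only member changed by 2-fold or more, so that call does not show a fall across the list. The median and the camera direction differed in sign for the androgen, ion channel, ribosomal, leukocyte and neuronal lists, and the median and the mean for the growth factor and neuronal lists.

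**Figure D3:**
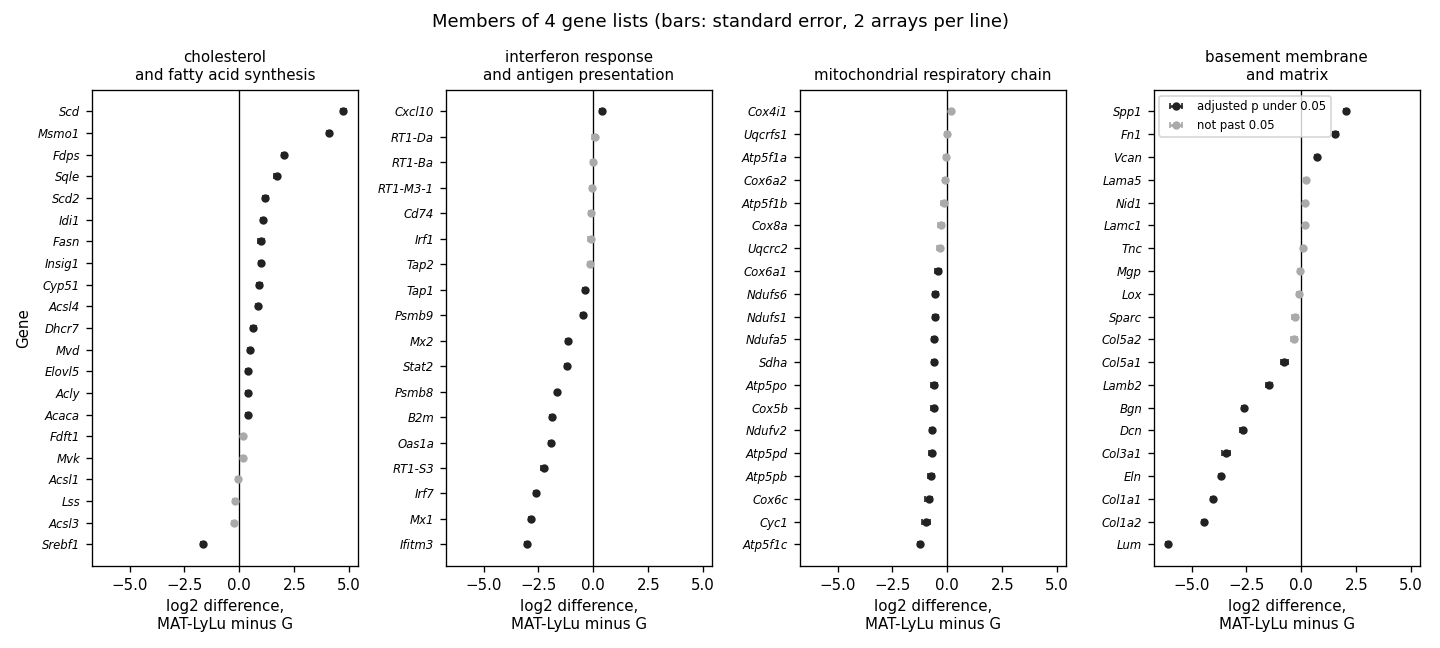
Log2 difference (MAT-LyLu minus G, horizontal axis) of each measured gene of 4 lists, with bars for the standard error of the limma fit over 2 arrays per line; black points passed an adjusted p of 0.05 and grey points did not. Msmo1 (4.06), Ifitm3 (-3.02) and Atp5f1c (-1.26) were measured above background on at least 1 array of each line, while points such as Scd and Lum, under it in 1 line, have no exact size.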

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

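Leaving out each array in turn left 1 array in a line, which was assumed to vary like the other line's. The counts then ran from 1664 to 2243 changed probe sets (684 to 1005 higher, 962 to 1308 lower), from 555 to 582 of 2-fold or more (216 to 268 higher, 288 to 353 lower) and from 973 to 1324 genes (399 to 602 higher, 561 to 726 lower), and 1 to 2 lists were higher and 3 lower. Against a minimum log2 difference of 1, limma's treat called 300 probe sets (136 higher, 164 lower) and 170 genes (81 higher, 89 lower), fewer because it tests a stricter hypothesis. With quantile normalization 1119 probe sets were higher and 1158 lower, with median scaling 1063 and 1171, and with cyclic loess 1038 and 1207, against 891 and 1318; among genes these were 707 and 694, 680 and 712, and 669 and 725, against 557 and 792, so the excess of falls depends on the scaling and turned among genes with quantile normalization. Of the 2209 calls, 2023, 2062 and 2096 remained under these scalings, and none changed sign. The number of lists higher was 1 in place of 2 without a filter, with the lower 50% left out, with median scaling and with the mean of all probe sets, in each case through the loss of the actin list. With an estimated correlation 0 lists were higher and 0 lower, and with fry 4 and 9. That correlation is estimated from 2 residual degrees of freedom, and no list passed with it. The matrix list lost its call although its estimate, -0.027, lay under the preset 0.01. That loss therefore does not show an effect of correlation among genes. The other called lists had estimates above the preset. These were 0.40 for sterol and fatty acid, 0.24 for respiratory chain, 0.17 for interferon and 0.16 for actin genes. Estimates of that size could undo calls, so for these lists the run neither shows nor excludes that correlation did so. The mesenchymal list gained a call with the mean of all probe sets (adjusted p = 0.039). Of 2046 results for 115 named genes over the alternatives, 1968 kept their side of the threshold. Direction had to be kept as well only for the 97 genes past the threshold in the main fit. Il6st, under the background level in both lines, turned from -0.35 to 0.024 with a floor at the background level, which also turned the sign of 32 of the 2209 calls and left 2021 probe sets changed. Same-numbered arrays of the lines deviated together with a correlation of 0.16 across probe sets; 2 pairs are too few to settle whether the numbers pair the samples, and the labels name no shared batch. With the replicate number as a block, 2353 probe sets were called. Dim probe sets and the signal ceiling limit folds: 505 tested probe sets were under the background level on all arrays and 27 saturated on all.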

Other observations

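The tests on the interferon genes, on the signal ceiling, on whole chromosomes and on families of gene symbols, and the genes of this paragraph, were chosen only after the result was seen. The genes named here are single genes from no fixed list. Fosl1, a subunit of the AP-1 transcription factor, rose at least 7.59-fold (1088 ± 103 against 15799 ± 2474), Dusp6, a phosphatase of ERK kinases, at least 9.31-fold, Jun 3.58-fold (3 of its 4 probe sets) and Egr1 3.31-fold (2 of its 4 probe sets, with 1 of the 2 G arrays above background). Hprt1 rose at least 7.39-fold, Prps2 at least 2.12-fold and the transketolase gene Tkt 3.10-fold. Of the serine synthesis enzymes, Psat1 rose 3.18-fold while Phgdh was lower in all 3 of its probe sets (log2 difference -0.81 on the brightest). The fatty acid carrier Fabp5 (at least 7.12-fold), the gap junction gene Gja1 (at least 3.08-fold) and the cytokine gene Il33 (at least 4.76-fold) also rose. Lamp1 fell 5.86-fold (2 of its 3 probe sets), the acid glucosidase gene Gaa from 22560 ± 2144 to 5616 ± 391 and the ceramidase gene Asah1 at least 5.99-fold, while the lysosomal protease gene Ctsl rose by a log2 difference of 1.14 on its brightest probe set, 1 of 2. The class I genes RT1-A and RT1-CE12, whose probe sets can match related transcripts, were 3.18-fold and 3.61-fold lower, and Casp1 and the interferon-inducible GTPase Irgm2 at least 5.46-fold and 2.48-fold lower. The probe sets of Dusp6, Egr1, Hprt1, Fabp5, Gja1 and Casp1 can match related transcripts as well. Apart from Phgdh (1.1e-04) and Ctsl (1.6e-05), each of these genes had an adjusted p of 6.5e-06 or less by limma. Picked by their values, they are no test of a pathway.

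Gene families formed by the letters of the symbol, 72 families with at least 6 genes measured, were tested with camera. The family of symbols that start with Ndufa, mostly complex I subunits but with Ndufa4 and Ndufa4l2 among them, passed (6 of 7 genes lower, none higher, median log2 difference -0.97, adjusted p = 0.0031; adjusted p = 0.98 with an estimated correlation). The Ndufb family had 8 of 9 genes lower with an adjusted p of 0.13.

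Genes that sit next to each other on a chromosome tended to move together. Over 3832 pairs of neighbouring measured genes, ordered by the GRCr8 annotation, the log2 differences correlated at 0.099, where the upper bound of the central range of 10000 permuted orders was 0.031 (1-sided permutation p = 1e-04, the smallest they can give, adjusted p = 6e-04; genes are not independent replicates). Clusters of related genes may explain such a pattern. Without pairs that share the first 3 characters of their symbol the correlation was still 0.083, above the permuted range. That filter keeps related neighbours whose first 3 characters differ, such as Mx1 and Mx2, so it cannot exclude clusters of related genes. It argues only against pairs with the same first 3 characters as the whole cause. Segments gained or lost in 1 line would reach further. Without such pairs the correlation at 10 places apart was 0.060 against a permuted 0.032, though at 5 places it was 0.012 and within the permuted range. At 2, 3 and 20 places it was 0.063, 0.039 and 0.038, each above its permuted bound of 0.032 to 0.033. The rank correlation was 0.057 at 5 places and 0.033 at 10 places, each against 0.032, and 0.062 at 20 places against 0.033. On the chromosome that carries Tfrc, Mx1 and Mx2, 38 of 96 measured genes were lower and 3 higher (camera adjusted p = 4.8e-04 over 21 chromosomes), and on the one that carries Odc1, Id2 and Sdc1, 53 of 163 were higher and 13 lower (adjusted p = 0.0025). The chromosome of Spp1 and Sod3 (33 of 121 higher, 13 lower, adjusted p = 0.018) and that of Lum and Krt8 (32 of 279 higher, 88 lower, adjusted p = 0.049, lost under quantile and loess scaling and without G replicate 0, G replicate 1 or MAT-LyLu replicate 1, at 0.051 to 0.068) also passed. The first pair kept an adjusted p between 2.3e-04 and 0.0071 under quantile, median and loess scaling and with each array left out, and the chromosome of Spp1 one between 0.019 and 0.036; none of the 4 passed with an estimated correlation (0.79 to 0.81). The run of neighbours Ttc3, Dyrk1a, Kcnj15, Pcp4, Mx1, Mx2, Col8a1 and Cmss1, the lowest found, had a median of -1.30, with Mx1 and Mx2 both of the interferon list. The lowest run of 8 genes in 100 permuted orders had -1.31 and the median of their lowest runs was -0.71, and 1 of the 100 orders reached as low a run. The overlapping run from Dyrk1a to Tbc1d23 had -0.92, which 11 of the 100 orders reached. A difference in chromosome copies between the lines is a hypothesis for these values, and the correlations are divided on it. Those at 10 and 20 places lay above their permuted bounds. The 0.012 at 5 places lay within the permuted range, while the rank correlation of 0.057 there lay above its bound. No DNA was measured here that could test this hypothesis, and shared regulation of neighbours was not tested.

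The fall of interferon and antigen presentation genes was weighed against 3 explanations. Leukocytes in the G samples would bring their own markers, but the lowest log2 difference among the 12 leukocyte markers was -0.14, for Cd4, against a list median of -0.80, which argues against them. Scaling between arrays does not account for it either, since the median nearest 0 under quantile, median and cyclic loess scaling was -0.71. Whether the 11 falls belong to the line or to the state of its cultures cannot be told apart, because the labels name no separate cultures. A lower interferon programme in MAT-LyLu is therefore a hypothesis that independent cultures could test.

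One array stood apart at the bright end. The highest signal on G replicate 1 was 1.36 times that of the next array, and its 9 hybridisation spike-in probe sets were brighter than on any other array, by a median of 1.26 times the mean of the others, while the median ratio of the rat probe sets was 1.00. More spike-in material would not have raised the ceiling, so it is unlikely to be the whole cause. An upward rescaling of the whole array would raise the ceiling and all spike-ins by 1 factor, but the spike-in ratios ran from 1.15 to 1.66, a spread of 1.44 times against at most 1.20 times on the other arrays, so rescaling alone does not account for them and its part stays open. Without that array 2081 probe sets were called in place of 2209, 1902 of them shared. Vim read 38640 on G replicate 0 and 51873 on this array.

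Of 1140 genes with several tested probe sets, 323 had at least 2 that changed. For 13 of these 323, probe sets changed in opposite directions, Ccnd1, Tpm3 and Hk2 among them. For Hk2 the log2 differences were -0.57 and 0.95.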
